A study of Mus musculus with 12 samples.

How the data were processed

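RNA was measured in 12 libraries of MIN6 cells, a line from a mouse insulinoma that serves as a model of pancreatic beta cells. Per the labels, cells at passage 29 were nucleofected with an siRNA against Pdx1 or with a control siRNA called NT and harvested after 72 h. RNA came from a TRAP procedure, translating ribosome affinity purification, which pulls ribosomes down through a tagged ribosomal protein together with the mRNAs they carry. Each culture condition gave IP RNA (bound to the purified ribosomes) and total RNA, which makes 4 groups of 3 libraries. The tagged protein, the library kit and the strand of the reads are not given in the sources used here.

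The authors deposited 1 table of raw counts per library, with whole-number counts of reads per RefSeq transcript and no normalization. TopHat2, featureCounts and the genome build mm10 are named in the submitters' processing notes, without versions. Whether reads with several matches in the genome were counted, and whether strand was used, is not given there, so genes that overlap on opposite strands cannot be told apart. The tables share 17133 transcripts, of which 16292 are protein-coding and 841 non-coding accessions. The lowest total over the 12 libraries was 141 counts, so transcripts below some minimum are not analysed here. The 58 largest values carry 6 significant digits.

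Transcripts were matched to gene symbols through a RefSeq gene table of GRCm38.p6, the assembly behind mm10. A symbol was found for 16838 transcripts. The other 295, which held 0.58% to 0.83% of a library's counts, were left out. A read lying in several transcripts of a gene is counted in each of them, as the nearly equal counts of the Ins2 transcripts show. Each gene was therefore represented by its transcript with the highest total, which gave 12643 genes, of which 2634 had more than 1 transcript. Summed over these genes the libraries held 29430690 to 45806807 counts. A count table summarises reads after PCR without molecular identifiers, so counting error is the lower limit of the true error.

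Genes were tested with edgeR 4.0.16 in R 4.3.3. All libraries entered a single quasi-likelihood fit with a mean per group, TMM normalization and the default expression filter by group, which removed 0 genes. Contrasts were the siRNA effect in total RNA, the siRNA effect in IP RNA, the difference between these effects (an interaction), and IP against total RNA under each siRNA. P-values were adjusted by the Benjamini-Hochberg method over all 12643 genes, and an adjusted p under 0.05 counted as changed. Standard errors were derived from the log2 fold change and the F statistic. Levels are CPM as computed by edgeR on TMM-scaled library sizes, as mean ± SD of 3 libraries. Adjusted p-values of genes in the text come from this edgeR test unless another test is named.

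The groups, contrasts, 24 gene lists, alternatives and the rule for named genes were fixed before the data were examined. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01 between genes, adjusted over the lists of a contrast, and again with an estimated correlation and with fry. A list needed 5 measured members, which 22 lists had. No member was measured of the list of mitochondrially encoded mRNAs or of the list of immune, endothelial and stromal markers. The rule for named genes took Pdx1, Rpl10a, Ins1, Ins2, Mafa, Slc2a2, Atf4, Atf5, Ddit3 and Hspa5. It added the 6 genes with the highest and the 6 with the lowest log2 fold change per contrast among genes past the test with a mean of at least 5 CPM and, between 2 groups, no overlap of their libraries. A gene among these is not reported here. It also added up to 4 members of each list with the smallest p among those past the test. Unnamed gene models were passed over.

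Genes whose reads could belong elsewhere were marked with minimap2 2.31 on GENCODE M21 transcripts. A gene counted as having a near-identical copy when alignments of at least 100 bases and 95% identity to annotated transcripts outside its own locus covered at least 50% of its transcript. This held for 444 genes. Copies without an annotated transcript were not seen. Exons shared with another annotated gene were measured for all named genes. Figures and tables were made with Python 3.11.15.

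The tests were run on simulated data first, with counts drawn from the real means and library sizes and known fold changes put into 50 genes per size. In total RNA the edgeR test recovered 14% of genes changed 1.25-fold, 82% at 1.5-fold and 100% at 2-fold. In IP RNA it recovered 18%, 90% and 90%. For the interaction it recovered 0%, 34% and 84%. For IP against total RNA it recovered 34%, 80% and 96% with NT siRNA, and 26%, 80% and 96% with Pdx1 siRNA.

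Alternatives were RLE and upper-quartile scaling, the DESeq2 1.42.0 Wald test and no expression filter. Further settings were a filter of 1 CPM in 3 libraries, Ins1 and Ins2 left out, the replicate number as a block, a fit on only the libraries compared, and each library left out in turn. After the data were seen, 4 more were added. These were a mapping batch as a term, a restriction to the IP libraries of 1 mapping batch, genes with copies left out, and the transcript with the lowest total per gene. The mapping batch is inferred from counts at genes with copies, since the labels name no batch: it sets replicate 3 of NT IP and all 3 Pdx1 siRNA IP libraries against the other 8.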

Results

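The series measured how depletion of Pdx1, the homeodomain transcription factor that drives insulin gene expression in beta cells, changes the RNA of MIN6 insulinoma cells. RNA bound to purified ribosomes (IP) and total RNA were sequenced 72 h after nucleofection with NT or Pdx1 siRNA, with 3 libraries in each of the 4 groups. Libraries held 29430690 to 45806807 counts over 12643 genes. The insulin genes Ins1 and Ins2 together took 9.33% to 10.2% of the counts in NT total RNA, and 6.69% to 7.36% in Pdx1 siRNA total RNA. Their share was 15.3% to 18.0% in NT IP RNA and 11.9% to 13.7% in Pdx1 siRNA IP RNA. Replicates of a group correlated across genes at r = 0.985 to 0.998 on the log scale, and no pair agreed within sampling noise (chi-square per degree of freedom of 5.7 or more). The labels do not say whether replicates were separate cultures, so all p-values measure only the spread between these libraries, which may be technical.

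A set of 4 IP libraries, replicate 3 of NT and all 3 of Pdx1 siRNA, stood apart at genes with near-identical copies elsewhere in the genome. Rpl32l, a retrogene copy of a ribosomal protein gene, held 1726 and 1260 counts in NT IP replicates 1 and 2 but 29 in replicate 3, and 33, 37 and 22 in the Pdx1 siRNA IP libraries. It held 699 to 1131 counts in the 6 total RNA libraries. Against NT IP replicates 1 and 2, replicate 3 was lower by more than 2-fold at 72 of 444 genes with a copy, and 17.1% of those genes differed by more than 2-fold in either direction. Among 11600 genes with under 10% of the transcript matched elsewhere the share was 0.47%. The set does not part from the others at every such gene: Tpt1 held 405 counts in NT IP replicate 3 but 3218, 2963 and 4412 in the Pdx1 siRNA IP libraries. The share of counts at genes with a copy was 1.90% to 2.35% in the 4 libraries, 3.15% and 3.40% in the other two IP libraries, and 1.96% to 2.43% in Pdx1 siRNA total RNA. This split is called the mapping batch here, and no total RNA library belongs to the set of 4.

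**Figure D1:**
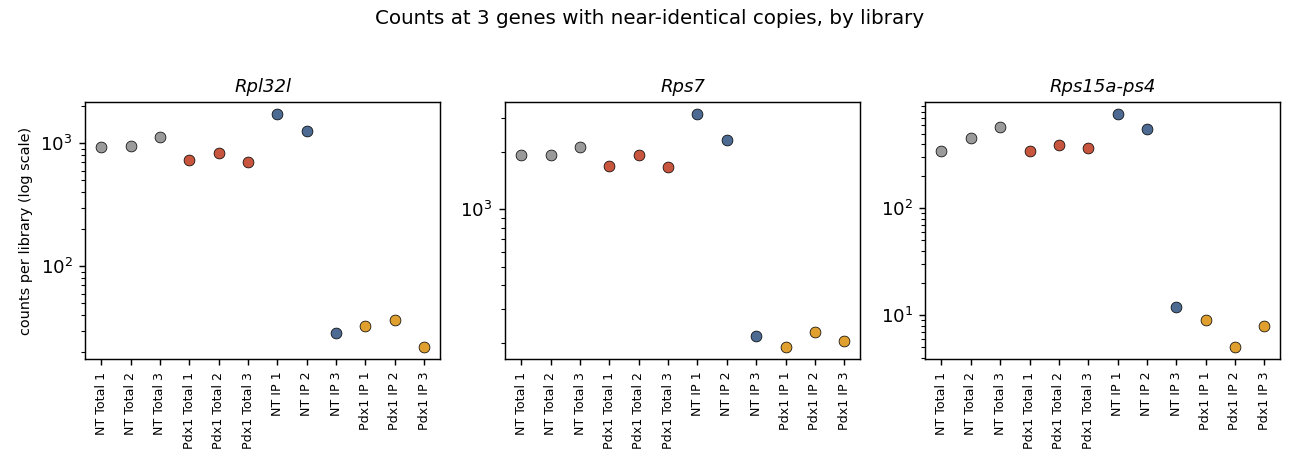
Counts per library (log axis) at Rpl32l, Rps7 and the pseudogene Rps15a-ps4, 3 genes with near-identical copies chosen after their values were seen; each point is 1 library. NT IP replicate 3 and the 3 Pdx1 siRNA IP libraries lie far below the other 8, at 22 to 37 counts for Rpl32l against 699 to 1726.

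Pdx1 itself (chromosome 5, 147270097 to 147275848, build mm10) was lower in every Pdx1 siRNA library than in every NT library. In total RNA its level fell from 117 ± 6.89 CPM (SD, n = 3; 118, 123 and 110 CPM) to 51.0 ± 5.54 CPM (47.6, 57.4 and 47.9 CPM), which is 2.29-fold lower (log2 fold change −1.20, SE 0.10, adjusted p = 1.0e-07, edgeR). In IP RNA it fell from 110 ± 5.84 CPM (104, 115 and 111 CPM) to 45.5 ± 5.84 CPM (50.6, 46.7 and 39.2 CPM), 2.42-fold lower (−1.27, SE 0.10, adjusted p = 4.3e-08). The knockdown did not differ between the fractions by more than its error (difference −0.08, SE 0.14, adjusted p = 0.814). Pdx1 in IP and total RNA of NT cells differed by −0.09 (SE 0.10, adjusted p = 0.435).

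The first comparison asked which transcripts change in total RNA after Pdx1 depletion. The glucagon gene Gcg (chromosome 2, 62474530 to 62483653) rose 3.98-fold, from 763 ± 19.1 to 3037 ± 219 CPM (SD, n = 3). Chgb (chromosome 2, 132781642 to 132795079), which encodes the granule protein chromogranin B, rose 3.73-fold from 8079 ± 436 to 30130 ± 5163 CPM. Mafa (chromosome 15, 75745501 to 75748321), a transcription factor of mature beta cells, fell 1.92-fold from 78.0 ± 14.0 to 40.5 ± 6.38 CPM. The mitotic cyclin Ccnb2 fell 4.06-fold, from 54.4 ± 2.01 to 13.4 ± 1.28 CPM. The p53 target Cdkn1a (chromosome 17, 29090979 to 29100722), an inhibitor of cyclin-dependent kinases, rose 2.82-fold from 44.5 ± 1.68 to 126 ± 6.46 CPM. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment called 6696 of 12643 genes changed, 3010 higher and 3686 lower, of which 886 changed 2-fold or more (427 higher and 459 lower). More genes were higher than lower with upper-quartile factors (3432 against 3043) and without NT total replicate 1 (2923 against 2693), 2 (3063 against 2881) or 3 (2922 against 2656), so neither direction can be called the more frequent.

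Among genes past the test with a mean of at least 5 CPM, the highest fold changes in total RNA belonged to genes that were low in NT cells. Lcn2 (chromosome 2, 32384637 to 32387739), encoding the iron-siderophore binding protein lipocalin 2, rose 19.7-fold from 1.27 ± 0.25 to 25.4 ± 7.31 CPM (log2 fold change 4.30, SE 0.27, adjusted p = 4.4e-09). Serpina7, encoding thyroxine-binding globulin, rose 18.5-fold, the protease inhibitor gene Serpine2 15.3-fold, Podn 11.2-fold and Clec2d 10.5-fold. The carboxypeptidase gene Cpz went from 0.894 ± 0.193 to 14.4 ± 2.59 CPM. The genes with the lowest log2 fold changes included Troap (−2.32), the phosphatase gene Cdkn3 (−2.29), the mitotic kinesin gene Kif2c (−2.20), Sapcd2 (−2.18) and Cenpa (−2.18), which encodes the centromeric histone. Ldha (chromosome 7, 46842274 to 46855627), encoding lactate dehydrogenase A, fell 4.45-fold with a wide spread (log2 fold change −2.15, SE 0.41). The Pdx1 siRNA libraries held 24.7, 94.5 and 84.0 CPM and the NT libraries 268, 342 and 298 CPM. Apart from Rpl10a, the libraries of both groups did not overlap for any gene named in this comparison. Such a separation is shown by 10% of genes by chance. The rule also required it of the genes with the largest changes, and list members were taken by the smallest p, so it is no added evidence.

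**Figure D2:**
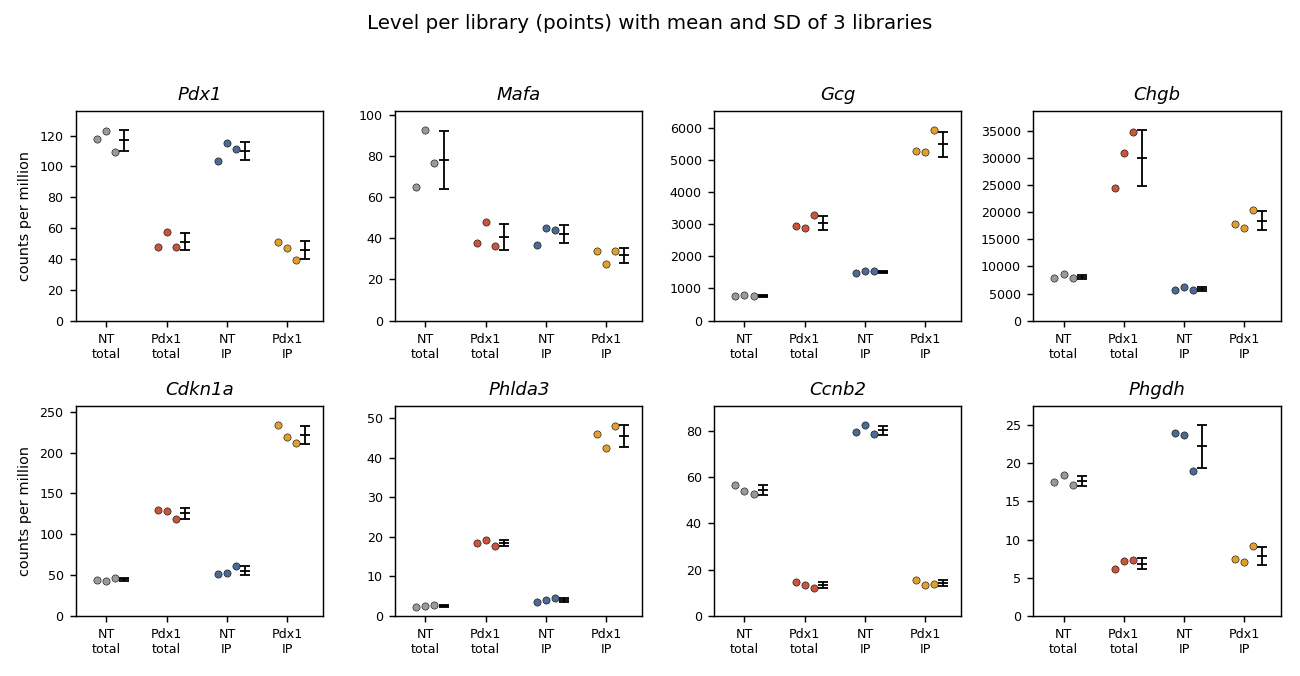
Level of 8 genes in CPM (linear axes from 0); points are libraries, and the bar beside them is the mean with its SD over 3 libraries of each group. Pdx1, Ccnb2 and Phgdh were lower and Gcg, Chgb, Cdkn1a and Phlda3 higher in all Pdx1 siRNA libraries of both fractions than in the NT libraries of the same fraction.

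After TMM scaling the insulin genes moved little beside these, although their share of the counts fell as given above. TMM factors were 1.22 to 1.231 in NT total and 0.95 to 1.066 in Pdx1 siRNA total RNA. They were 0.984 to 1.011 in NT IP and 0.752 to 0.866 in Pdx1 siRNA IP RNA. The fold changes of the insulin genes depend on this scaling and are smaller than the fall in their share. In total RNA Ins1 fell by 0.39 on the log2 scale (SE 0.11, adjusted p = 0.00901), and without NT replicate 1 it was at −0.32 (adjusted p = 0.0618). Ins2 was at −0.16 (SE 0.14, adjusted p = 0.339) and passed no test. The insulin and secretory granule list rose as a group (camera, adjusted p = 0.000349, but 0.548 as an adjusted p with an estimated correlation). Of its 22 members, 16 rose and 3 fell (16 and 3 adjusted over the list alone), with a median log2 fold change of 0.73. Chgb (1.90) and the prohormone convertase chaperone gene Scg5 (1.12) rose, while the neuropeptide gene Npy fell by 1.94.

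All 7 measured markers of other islet endocrine cells rose in total RNA (7 adjusted over the list alone, median 1.43, camera adjusted p = 8.5e-10; adjusted p = 0.0148 with an estimated correlation). Gc (vitamin D binding protein, an alpha-cell marker) rose 3.99-fold, the transthyretin gene Ttr 2.69-fold and the pancreatic polypeptide gene Ppy 4.39-fold, though only from 0.572 ± 0.151 to 2.53 ± 0.50 CPM. The list of beta-cell transcription factors gave 3 of 20 higher and 7 lower (the same counts adjusted over the list alone; median −0.17, camera adjusted p = 0.522). In it Mafa (−0.94, SE 0.14, adjusted p = 3.2e-05) and Bach2 (−1.05) fell, and Hnf4a rose (0.58). Of 17 reported PDX1 target genes 5 rose and 6 fell (6 and 7 adjusted over the list alone; median −0.20, camera adjusted p = 0.689). The calcium pump gene Atp2a2 (−0.57) and the glucose transporter gene Slc2a2 (−0.33, SE 0.09, adjusted p = 0.00793) fell, and Wfs1 rose (0.49). Without NT replicate 2 the Slc2a2 value was −0.19 with an adjusted p of 0.0997. The list of glucose sensing and exocytosis genes gave 12 of 24 higher and 4 lower (12 and 5 adjusted over the list alone; median 0.17, camera adjusted p = 0.108). Members included the collectrin gene Cltrn (1.90) and the cation channel gene Trpm5 (−1.28).

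Stress pathways went in different directions in total RNA. Of 30 genes of the ATF4 and integrated stress response list, 22 fell and 1 rose (23 and 1 adjusted over the list alone; median −0.67, camera adjusted p = 4.0e-07; adjusted p = 0.215 with an estimated correlation). Atf4 fell by 0.74 (SE 0.10), Atf5 by 1.03 (SE 0.07), Ddit3, encoding CHOP, by 0.70 (SE 0.09). The serine synthesis genes Psat1 and Phgdh fell by 1.15 and 1.37, although 84.6% of the Phgdh transcript matches a copy elsewhere, which leaves its counts uncertain. Among 20 cytosolic aminoacyl-tRNA synthetases 12 fell and 1 rose (12 and 1 adjusted over the list alone; median −0.22, camera adjusted p = 0.0619), with Nars at −0.64. Genes of ER chaperones and the unfolded protein response rose instead, 16 of 31 higher and 2 lower (16 and 2 adjusted over the list alone; median 0.24, camera adjusted p = 0.029; adjusted p = 0.869 with an estimated correlation, and a median of 0.15 and 0.0995 without Pdx1 siRNA total replicate 3). Hspa5, encoding the chaperone BiP, rose by 0.47 (SE 0.10, adjusted p = 0.00141), Xbp1 by 0.58 and Dnajb9 by 0.80.

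Cell cycle genes fell nearly throughout. Of 33 members 30 fell and 0 rose (30 and 1 adjusted over the list alone; median −1.62, camera adjusted p = 9.8e-44; adjusted p = 0.0148 with an estimated correlation). These include Ccnb2 (−2.02, SE 0.08), the spindle assembly gene Tpx2 (−1.86, SE 0.09) and the replication licensing gene Mcm3 (−1.67, SE 0.08). The apoptosis and p53 response list rose, with 13 of 22 higher and 4 lower (13 and 4 adjusted over the list alone; median 0.36, camera adjusted p = 8.3e-07; adjusted p = 0.00913 with an estimated correlation). Phlda3 (chromosome 1, 135766085 to 135769134), a p53-induced inhibitor of AKT, rose 7.61-fold (log2 fold change 2.93, SE 0.10, adjusted p = 2.0e-11), Trp53inp1 3.05-fold and Zmat3 2.12-fold. Glycolysis and hypoxia response genes fell, with 15 of 20 lower and 2 higher (15 and 2 adjusted over the list alone; median −0.76, camera adjusted p = 0.00267; adjusted p = 0.664 with an estimated correlation). In this list Tpi1 (−1.16) and the kinase gene Pdk1 (−1.17) fell, as did the mitophagy receptor gene Bnip3 (−1.76), of which 94.2% matches a copy elsewhere.

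**Figure D3:**
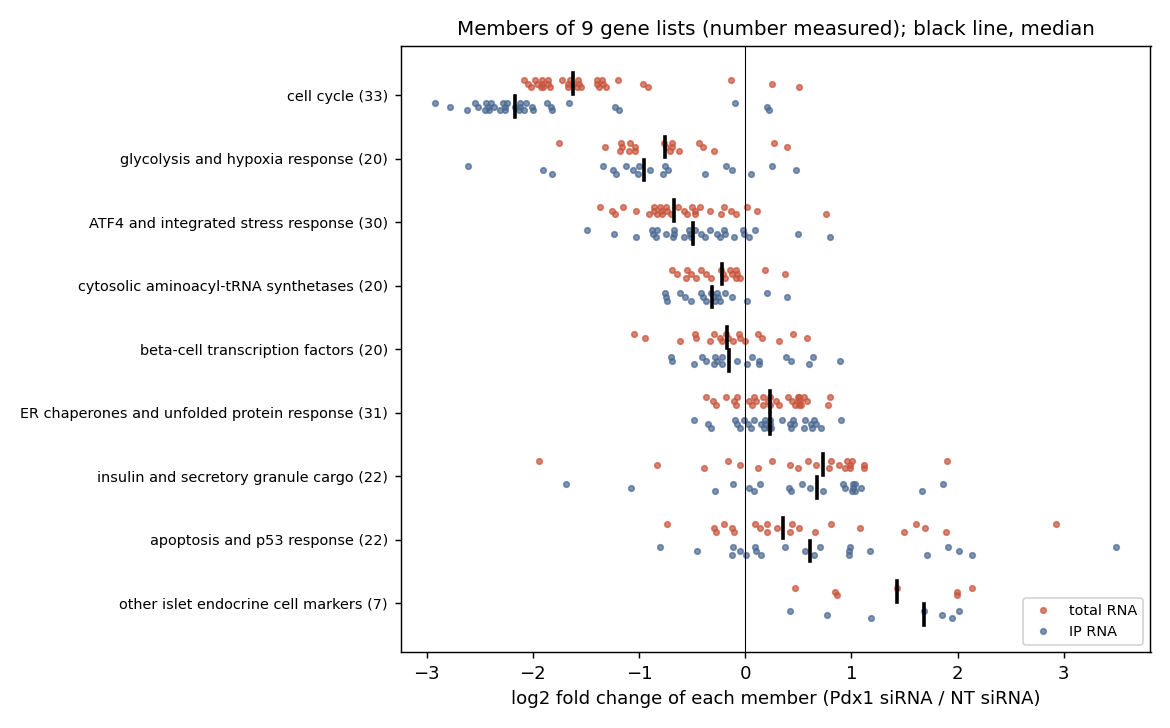
Log2 fold change, Pdx1 siRNA against NT siRNA, of each measured member of 9 gene lists in total RNA (red) and IP RNA (blue); the black line is the list's median and the number in parentheses the members measured. Cell cycle genes have the lowest medians (−1.62 and −2.16) and other islet endocrine markers the highest (1.43 and 1.68) in both fractions.

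The second comparison asked the same in ribosome-bound RNA, that is, in IP RNA. Gcg rose 3.62-fold, from 1520 ± 23.8 to 5494 ± 389 CPM (SD, n = 3). Cdkn1a rose 4.03-fold from 55.0 ± 5.39 to 222 ± 11.1 CPM and Phlda3 11.3-fold (log2 fold change 3.50, SE 0.10, adjusted p = 5.2e-12). Ccnb2 fell 5.71-fold, from 80.3 ± 2.05 to 14.1 ± 1.28 CPM, and Slc2a2, encoding the glucose transporter GLUT2 (chromosome 3, 28697903 to 28728361), fell 1.98-fold from 15.1 ± 1.63 to 7.59 ± 0.16 CPM. Lcn2 (26.8-fold), Serpine2 (15.6-fold), Serpina7 (15.3-fold), Cpz (14.9-fold), Podn (14.1-fold) and Clec2d (12.8-fold) again had the highest fold changes among genes with a mean of at least 5 CPM. edgeR called 7542 of 12643 genes changed, 3694 higher and 3848 lower (3811 and 3712 with upper-quartile factors), and 1197 by 2-fold or more. With the mapping batch as a term the count was 5212, and 4900 within the 4 IP libraries of a single mapping batch. In both, the siRNA effect in IP RNA and the interaction compare Pdx1 siRNA IP with NT IP replicate 3, a single library that is assumed to vary like the other groups.

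Among the low fold changes in IP RNA was Lars2, a mitochondrial leucyl-tRNA synthetase gene, at −6.32 (SE 1.17). Its NT IP libraries held 13833, 354753 and 5545 counts, and without NT IP replicate 2 it was at −2.51. With the mapping batch as a term Lars2 was at −1.75 with an adjusted p of 0.102. At other genes with low fold changes the mapping batch parts the libraries. Wdr89 went from −3.56 to −0.32 (adjusted p = 0.151) with that term. The ribosomal protein gene Rpl35 went from −3.63 to −0.17 (adjusted p = 0.641), Rps10 from −3.13 to −0.08 (adjusted p = 0.799) and Rpl37 from −2.95 to 0.02 (adjusted p = 0.955). Rpl35 is uncertain also because 66.2% of its exons are shared with Wdr38 and Arpc5l on the opposite strand. Libraries of both groups overlapped at Rpl35, Rps10, Rpl37, Rpl10a and Ins2, and at no other gene named in this comparison. The mitotic genes Bub1 (−2.78, SE 0.12), Cdkn3 (−2.76, SE 0.16), Prr11 (−2.63, SE 0.14) and Ccnb1 (−2.92, with a copy matching 51.9% of its transcript) stayed past the test with the batch as a term.

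**Figure D4:**
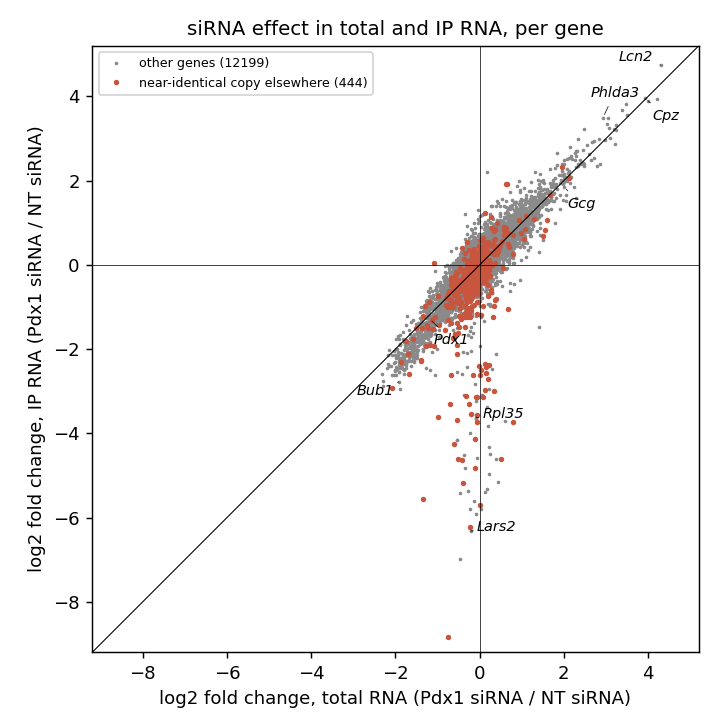
Log2 fold change, Pdx1 siRNA against NT siRNA, in total RNA (x axis) and IP RNA (y axis) for 12643 genes, with 444 genes that have a near-identical copy in red and the line of equal change. Most genes follow the line (r = 0.821 across genes), and a tail of genes near 0 in total RNA reaches far below 0 in IP RNA, among them Lars2 (−6.32) and Rpl35 (−3.63).

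Among beta-cell genes in IP RNA, Ins1 was at −0.28 (SE 0.11, adjusted p = 0.0415) and Ins2 at 0.04 (SE 0.14, adjusted p = 0.835). Leaving out Pdx1 siRNA IP replicate 1 or 2, or any NT IP library, put the adjusted p of Ins1 between 0.0732 and 0.155, at log2 fold changes of −0.31 to −0.19. The mapping batch as a term gave −0.34 (adjusted p = 0.126). Mafa fell by 0.40 (SE 0.14, adjusted p = 0.0193), with −0.36 (0.063) without NT IP replicate 2 and −0.31 (0.0944) without Pdx1 siRNA IP replicate 2. Nkx2-2, a transcription factor gene of endocrine progenitors and beta cells, rose (0.89, SE 0.07). The granule list rose, with 15 of 22 higher and 3 lower (15 and 3 adjusted over the list alone; median 0.67, camera adjusted p = 0.00205; adjusted p = 0.654 with an estimated correlation). Chgb was at 1.66, Npy at −1.69 and Sytl4, a granule docking gene, at −1.07. All 7 other islet endocrine markers rose (7 adjusted over the list alone; median 1.68, camera adjusted p = 1.7e-08; adjusted p = 0.0276 with an estimated correlation), and Gc was at 2.01, Ttr at 1.68 and Irx1 at 1.19. Beta-cell transcription factors gave 5 of 20 higher and 9 lower (5 and 9 adjusted over the list alone), with a median of −0.15 and a mean of −0.04 while camera pointed up (adjusted p = 0.992).

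Cell cycle genes fell in IP RNA with a median of −2.16, 30 of 33 lower and 0 higher (30 and 0 adjusted over the list alone; camera adjusted p = 3.3e-58; adjusted p = 0.0106 with an estimated correlation). Tpx2 was at −2.41 (SE 0.09). The apoptosis and p53 response list rose with 13 of 22 higher and 2 lower (13 and 2 adjusted over the list alone; median 0.61, camera adjusted p = 1.7e-08; adjusted p = 0.00382 with an estimated correlation). Trp53inp1 was at 1.72. The ATF4 list fell, 19 of 30 lower and 2 higher (19 and 2 adjusted over the list alone; median −0.49, camera adjusted p = 0.000741; adjusted p = 0.45 with an estimated correlation). Its members Atf4 (−0.52, SE 0.10), Atf5 (−0.52, SE 0.07), Ddit3 (−0.42, SE 0.09), Psat1 (−1.24) and Phgdh (−1.49) fell. Aminoacyl-tRNA synthetases fell, 16 of 20 lower and 2 higher (16 and 2 adjusted over the list alone; median −0.31, camera adjusted p = 0.0185; adjusted p = 0.654 with an estimated correlation), with Nars at −0.73. Glycolysis and hypoxia genes fell, 14 of 20 lower and 2 higher (14 and 2 adjusted over the list alone; median −0.95, camera adjusted p = 0.00232; adjusted p = 0.654 with an estimated correlation). Tpi1 was at −1.33 and, less certain for copies matching 85.6% and 94.2% of their transcripts, Eno1 at −1.91 and Bnip3 at −1.81. ER chaperone genes gave 14 of 31 higher and 3 lower (14 and 3 adjusted over the list alone; median 0.23, camera adjusted p = 0.0552), with Xbp1 higher (0.72) and Hspa5 at 0.23 (SE 0.10, adjusted p = 0.0613). Hspa5 passed without Pdx1 siRNA IP replicate 2 (0.0351), with upper-quartile factors (0.0407), with DESeq2 (0.0166) and with a replicate block (0.0468).

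Across genes the siRNA effects in IP and total RNA correlated at Pearson r = 0.821 and Spearman rho = 0.859, a description since genes are not independent, and at r = 0.968 over the 5479 genes called in both. These comparisons share no library, but IP and total RNA may come from the same cultures, which the labels leave open. Variation between cultures could then raise the correlation and the overlap. Of the called genes, 2584 were higher in both fractions, where independent lists would share 879, and 2881 were lower in both, where independent lists would share 1122. Signs were the same at 5465 of the 5479 genes, with 2 higher in total and lower in IP RNA and 12 the reverse. The correlation was 0.857 without genes that have a copy and 0.913 with the mapping batch as a term or within the IP libraries of a single mapping batch.

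The third comparison, the interaction, asked where the siRNA effect differed between the fractions. Blm (chromosome 7, 80454993 to 80535148), encoding the Bloom syndrome helicase, fell further in IP RNA than in total RNA (difference −1.17, SE 0.12, adjusted p = 5.4e-04). The annealing helicase gene Smarcal1 was at 0.05 in total and −0.80 in IP RNA (difference −0.84, SE 0.10, adjusted p = 0.00246). Srebf1 (chromosome 11, 60199084 to 60224186), encoding a transcription factor of lipid synthesis, was at 0.06 in total and 1.17 in IP RNA (difference 1.11, SE 0.17, adjusted p = 0.0116). The mitotic genes Bub1 (−0.85), Mki67 (−0.75) and Melk (−0.71) and the cell cycle transcription factor gene E2f8 (−0.57) fell further in IP RNA. The AP-1 genes Jund (0.86) and Junb (0.74), Nkx2-2 (0.58) and the complex III gene Uqcrq (0.72) went the other way. So did H2aj (1.11), Prr7 (1.09), Il4i1b (1.00), Scand1 (1.15) and Cnbd2 (1.03). Scand1 shares 40.4% of its exons with Cnbd2 on the opposite strand, and Cnbd2 21.5% with Scand1 and an unnamed model, so reads in the shared parts cannot be assigned. Jund shares 52.6% of its exons with an antisense model and Il4i1b 86.3% with Tbc1d17, Nup62 and Atf5, so both are uncertain for the same reason. Across all genes the difference was more positive at higher GC content (r = 0.23, and −0.08 with log2 length). This trend was taken off the cell cycle list, but not off single genes or the other lists of the interaction.

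The edgeR test called 29 of 12643 genes in the interaction, 22 more positive and 7 more negative in IP RNA, with 2155 at an unadjusted p under 0.05. The split moved to 22 against 20 with RLE factors, 24 against 28 with upper-quartile factors and 24 against 30 without Ins1 and Ins2. With DESeq2, which changes the test along with the scaling, it was 142 against 185. A replicate block gave 373 genes (203 against 170), or 367 within siRNA (222 against 145), and 97 passed without genes that have copies (56 against 41). With the mapping batch as a term, and within the IP libraries of a single mapping batch, 5 genes passed, 4 of them among the 29. Blm, Smarcal1 and Cnbd2 were among these. The other 13 of the 16 genes named above as past the test lost the call, with adjusted p of 0.124 to 0.333 with the batch as a term and 0.125 to 0.45 within a single mapping batch. Their log2 differences with the term were 0.60 to 1.34 for the positive genes, from 0.58 to 1.15, and −0.89 to −0.56 for the negative, from −0.85 to −0.57. Of the 16, leaving out a library lost 13 without NT IP replicate 1 or NT total replicate 3, 12 without NT total replicate 1 and 11 without Pdx1 siRNA IP replicate 1. It lost 7 to 10 without NT IP replicate 2, NT total replicate 2, Pdx1 siRNA IP replicate 3 or Pdx1 siRNA total replicate 2 or 3, and 1 without Pdx1 siRNA IP replicate 2. Leaving out any of the 12 libraries moved the count by more than 1.5 times, to 4 without NT IP replicate 1 or NT total replicate 3, and 6 without NT total replicate 1. It was 9 to 18 without NT IP replicate 2, NT total replicate 2, Pdx1 siRNA IP replicate 1 or 3 or Pdx1 siRNA total replicate 2 or 3. The larger counts were 66 without Pdx1 siRNA IP replicate 2, 383 without Pdx1 siRNA total replicate 1 and 571 without NT IP replicate 3. Not past the test were Slc2a2 (−0.66, adjusted p = 0.0564), Atf5 (0.51, 0.0564), Mafa (0.54, 0.173), Atf4 (0.23, 0.436), Ddit3 (0.28, 0.258), Ins1 (0.11, 0.773), Ins2 (0.19, 0.642) and Hspa5 (−0.23, 0.436). Slc2a2 did pass with upper-quartile factors (adjusted p = 0.0463), with DESeq2 (0.00335), without Ins1 and Ins2 (0.046), without genes that have copies (0.0463) and with a replicate block (0.0138, or 0.0247 within siRNA). It also passed without NT IP replicate 3 (0.0114), NT total replicate 2 (0.0348) or Pdx1 siRNA total replicate 1 (0.023). Atf5 passed with DESeq2 (0.000569), without genes that have copies (0.0443), with a replicate block (0.0211, or 0.0295 within siRNA), and without NT IP replicate 3 (0.00755), Pdx1 siRNA IP replicate 2 (0.0497) or Pdx1 siRNA total replicate 1 (0.0341).

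As a group, cell cycle genes fell further in IP RNA, with a median difference of −0.49 (camera adjusted p = 9.7e-28; adjusted p = 0.091 with an estimated correlation) and 2 of 33 members past the all-gene test (26 adjusted over the list alone). Immediate early genes were more positive in IP RNA (median 0.26, 2 of 17 higher and 5 adjusted over the list alone, camera adjusted p = 3.2e-05; adjusted p = 0.162 with an estimated correlation). So were oxidative phosphorylation genes (median 0.17, 1 of 46 higher and 3 adjusted over the list alone, adjusted p = 0.000447; adjusted p = 0.612 with an estimated correlation, and a median of 0.21 and 0.0606 without NT IP replicate 3). Their median was 0.08 without Pdx1 siRNA IP replicate 1, 0.09 without NT total replicate 1 and 0.28 without Pdx1 siRNA total replicate 1. Atp5d (0.59, adjusted p = 0.0564) and Cox6a1 (0.55, adjusted p = 0.0593) did not pass alone, but both passed without NT IP replicate 3 (0.00694 and 0.0259), Pdx1 siRNA IP replicate 2 (0.0207 and 0.0273) or Pdx1 siRNA total replicate 1 (0.0359 and 0.0404). They also passed with DESeq2 (0.00233 and 0.000892), with a replicate block (0.0308 and 0.0251, or 0.044 and 0.033 within siRNA) and without genes that have copies (0.0463 for both). Small nucleolar RNA host genes had a median of 0.38 (0 of 11 past the test and 4 adjusted over the list alone, adjusted p = 0.00125; adjusted p = 0.612 with an estimated correlation), which was 0.23 without Pdx1 siRNA IP replicate 1 and 0.25 without Pdx1 siRNA total replicate 2. The apoptosis and p53 list had a median of 0.15 (0 of 22, 5 adjusted over the list alone, adjusted p = 0.00486; adjusted p = 0.091 with an estimated correlation), and of 0.07 without Pdx1 siRNA IP replicate 3 and 0.08 without NT total replicate 3. The ATF4 list was at 0.16 (0 of 30, 3 adjusted over the list alone, adjusted p = 0.00486; adjusted p = 0.612 with an estimated correlation). The ATF4 call was lost without Pdx1 siRNA IP replicate 3 (median 0.06, adjusted p = 0.0575) or Pdx1 siRNA total replicate 1 (median 0.09, adjusted p = 0.135), and the median was 0.06 without NT total replicate 3. Cytosolic ribosomal protein genes were more negative in IP RNA (median −0.29, 0 of 78 past the test and 14 adjusted over the list alone, adjusted p = 5.9e-05; adjusted p = 0.802 with an estimated correlation, and 0.106 without Pdx1 siRNA total replicate 1). That median was −0.11 without Pdx1 siRNA total replicate 1, −0.12 without NT IP replicate 1, −0.44 without Pdx1 siRNA IP replicate 1 and −0.45 without NT IP replicate 3. The sign turned around with the mapping batch as a term, to a median of 0.15 (adjusted p = 0.00465), and to 0.14 within a single mapping batch.

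The fourth comparison asked which RNAs were higher or lower on purified ribosomes than in total RNA of NT cells. Nuclear long non-coding RNAs were lower in IP RNA: Malat1 (chromosome 19, 5795690 to 5802672) was at 65.0 ± 13.1 CPM against 314 ± 41.7 CPM in total RNA (SD, n = 3), which is 4.84-fold lower. Neat1, the RNA scaffold of paraspeckles, was 3.99-fold lower, and Meg3 (chromosome 12, 109540996 to 109571729) 6.77-fold lower. Insulin mRNA was higher, Ins2 (chromosome 7, 142678656 to 142679726) 2.09-fold (log2 fold change 1.07, SE 0.14, adjusted p = 5.6e-06) and Ins1 1.88-fold, as were the amylin gene Iapp (1.92-fold), Gcg (1.99-fold) and Ppy (3.20-fold). The mRNAs of Slc2a2 (2.51-fold lower), the GLP-1 receptor gene Glp1r (2.51-fold lower) and Mafa (1.86-fold lower) were lower in IP RNA. Across all genes this ratio was lower for longer transcripts (r = −0.55 with log2 length). The 5 higher genes named have 500 (Ppy) to 1494 (Gcg) exon bases, Mafa 2739, Slc2a2 5755 and Glp1r 5811. No trend was taken off these single genes, so length and ribosome loading cannot be told apart for them. edgeR called 8810 genes, 4273 higher and 4537 lower, of which 264 were higher and 925 lower by 2-fold or more. The balance of all calls turned with RLE factors (4570 higher, 4279 lower), with DESeq2 (4536 and 4212), without Ins1 and Ins2 (4554 and 4288) and without NT IP replicate 2 (4273 and 4132). It also turned without NT total replicate 1 (4331 and 4081), 2 (4202 and 3869) or 3 (4247 and 3978).

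Mitochondrial and translation genes were higher in IP than in total RNA of NT cells. Of 46 nuclear-encoded oxidative phosphorylation genes 42 were higher and 1 lower (42 and 1 adjusted over the list alone; median 0.92, camera adjusted p = 1.1e-13; adjusted p = 0.231 with an estimated correlation). Sdhb was at 1.05, Ndufa5 at 1.23 and Cox4i1 at 1.22. After a trend on transcript length and GC content over all genes was taken off, the median was 0.42, with 4 of 46 below 0. Of 78 cytosolic ribosomal protein genes 59 were higher and 0 lower (59 and 0 adjusted over the list alone). The list's median was 0.75 (camera adjusted p = 1.8e-08, but adjusted p = 0.829 with an estimated correlation). With NT IP replicate 3 as the only NT IP library the median was 0.38, but no total RNA library shares its mapping batch. Without replicate 3 the median was 0.99, and with the mapping batch as a term 0.99, with 0 of 78 below 0. Rpl8 was at 1.09 and Rpsa at 1.30. After that trend was taken off, the ribosomal protein median was 0.23, with 22 of 78 below 0. Translation factors gave 27 of 43 higher and 2 lower (27 and 2 adjusted over the list alone; median 0.30, camera adjusted p = 0.00131; adjusted p = 0.826 with an estimated correlation), with Eif3k at 1.02 but Eif3a at −1.16. Nuclear-retained long non-coding RNAs gave 7 of 9 lower and 0 higher (7 and 0 adjusted over the list alone; median −0.99, camera adjusted p = 0.000396; adjusted p = 0.17 with an estimated correlation). Beta-cell transcription factors were lower, 13 of 20 against 2 higher (13 and 2 adjusted over the list alone; median −0.42, camera adjusted p = 0.00131; adjusted p = 0.78 with an estimated correlation). Among them were Mlxipl (−1.31), Rfx6 (−1.25), Rfx3 (−1.15) and Glis3 (−1.96). The stress genes Atf4 (0.59), Atf5 (0.55) and Ddit3 (0.71) were higher in IP RNA, and Hspa5 lower (−0.34, adjusted p = 0.00765, but −0.27 and 0.0589 without NT total replicate 2).

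Among genes with a mean of at least 5 CPM, those with the largest differences in NT cells were Tmem160 (1.63), S100a6 (1.62), Arhgdig (1.49) and Mir703 (1.38) on the higher side, with Pgk1 (1.90) and Rpl41 (1.81) less certain because copies match 68.8% and 87.2% of their transcripts. At Pgk1 replicate 3 of NT IP held 88.8 CPM and the other two 16.6 and 17.5 CPM, and without replicate 3 the Pgk1 value was 0.64. On the lower side were the mucin gene Muc4 (−3.37), the Golgi tether gene Trip11 (−2.81) and Mir124a-1hg (−2.78). Zbed6 (−3.56) lies with 100% of its exons inside another gene and Zfhx2os (−3.44) shares 95.2% with its antisense partner Zfhx2, so neither can be told from its neighbour. The prohormone convertase gene Pcsk1 (−0.83) and the activity-regulated gene Npas4 (−2.03) were lower, and Rpl10a was higher (0.31, SE 0.09, adjusted p = 0.00556), with a copy matching 78.8% of its transcript. The libraries of both groups overlapped at Pdx1 and at no other gene named here.

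**Figure D5:**
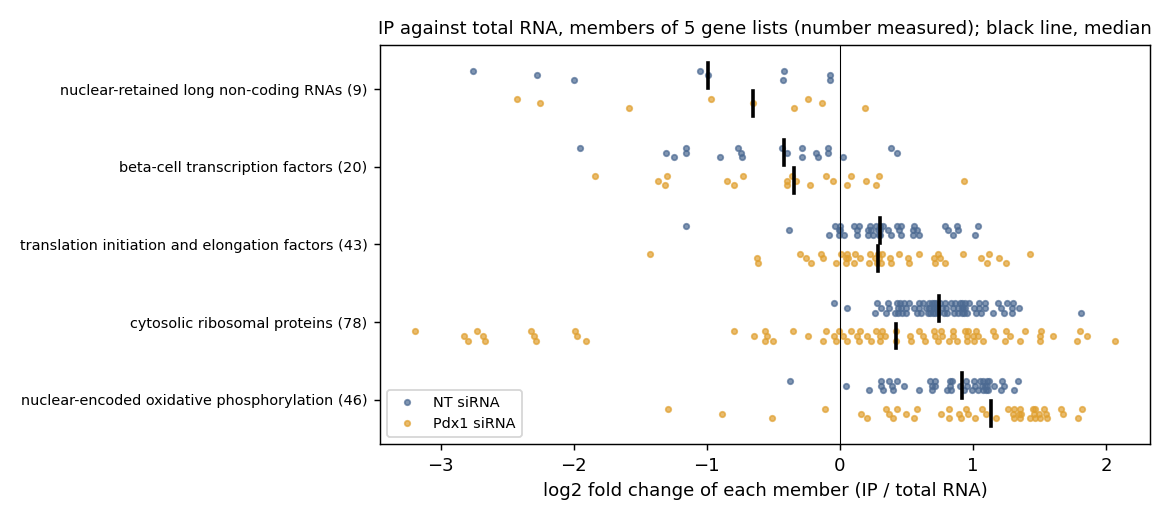
Log2 fold change of IP against total RNA for each measured member of 5 gene lists, with NT siRNA (blue) and Pdx1 siRNA (yellow); the black line is the list's median and the number in parentheses the members measured. Oxidative phosphorylation genes have medians of 0.92 and 1.13, and 12 ribosomal protein genes fall below 0 past the test with Pdx1 siRNA against 0 with NT siRNA.

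The last comparison set IP against total RNA in Pdx1 siRNA cells. Ins2 was 2.40-fold and Ins1 2.03-fold higher in IP RNA, and Slc2a2 3.96-fold lower, at 7.59 ± 0.16 CPM against 30.1 ± 2.70 CPM (SD, n = 3). No trend on transcript length was taken off these values either. Malat1 (4.76-fold lower) and Meg3 (5.37-fold lower) were again lower, and Mafa was at −0.36 (SE 0.14, adjusted p = 0.0273). It was at −0.26 (adjusted p = 0.129) without Pdx1 siRNA IP replicate 2, −0.22 (0.171) without Pdx1 siRNA total replicate 2 and −0.47 (0.111) with the mapping batch as a term, where the fold was larger and its error too. The stress genes Atf5 (1.06), Ddit3 (0.99), Atf4 (0.82) and Nupr1 (1.55) were higher in IP RNA. edgeR called 9490 genes, 4593 higher and 4897 lower. All 3 IP libraries here belong to the same mapping batch and no total library does, so the batch can be separated only through the NT libraries; with it as a term 6522 genes were called, 3324 higher and 3198 lower.

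In Pdx1 siRNA cells oxidative phosphorylation genes were higher in IP RNA in 40 of 46 cases and lower in 3 (41 and 3 adjusted over the list alone; median 1.13, camera adjusted p = 1.3e-13; adjusted p = 0.378 with an estimated correlation). Uqcrq was at 1.68 and Ndufb7 at 1.54. Cell cycle genes were lower, 23 of 33 against 3 higher (23 and 3 adjusted over the list alone; median −0.66, camera adjusted p = 0.0023; adjusted p = 0.814 with an estimated correlation). The kinesin gene Kif11 was at −1.59, Bub1b at −1.08 and the topoisomerase gene Top2a at −1.09. The ATF4 list was higher, 15 of 30 against 5 lower (15 and 5 adjusted over the list alone; median 0.30, camera adjusted p = 0.0176; adjusted p = 0.814 with an estimated correlation, and a median of 0.26 and 0.0699 without Pdx1 siRNA total replicate 1). Translation factors gave 25 of 43 higher and 4 lower (25 and 4 adjusted over the list alone; median 0.29, camera adjusted p = 0.0126; adjusted p = 0.814 with an estimated correlation), with Eif3k at 1.43 and Eif3a at −1.43. Nuclear-retained long non-coding RNAs gave 6 of 9 lower and 1 higher (6 and 1 adjusted over the list alone; median −0.65, camera adjusted p = 0.0138; adjusted p = 0.378 with an estimated correlation). Ribosomal protein genes gave 41 of 78 higher and 12 lower (41 and 12 adjusted over the list alone; median 0.42, camera adjusted p = 0.0023; adjusted p = 0.871 with an estimated correlation), with Rpl8 at 1.36. The 12 lower genes cannot be told apart from the mapping batch. With it as a term the list's median in the interaction went from −0.29 to 0.15.

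Tmem160 (2.02) and Arhgdig (1.84) again had high IP to total ratios in Pdx1 siRNA cells, as did, with copies matching 68.8% and 87.2% of their transcripts, Pgk1 (3.05) and Rpl41 (2.07). Pgk1 held 3167 counts in NT IP replicate 3 and 789, 1660 and 1658 in the Pdx1 siRNA IP libraries. In NT IP replicates 1 and 2 it held 628 and 588. The size of the Pgk1 ratio therefore cannot be told apart from the mapping batch. Muc4 (−3.41), Zbed6 (−3.77) and Zfhx2os (−3.87) were again lower. With the mapping batch as a term Lars2 went from −4.86 to 0.27, Rpl32l from −4.37 to 1.30 and Rpl35 from −3.19 to 0.81. For Lars2 this change may rest on NT IP replicate 2, which held 354753 counts against 13833 and 5545 in replicates 1 and 3 and weighs on the term. Snx9 went from 2.31 to 0.58 (adjusted p = 0.0989) with that term, Hspa5 from −0.57 to −0.43 (adjusted p = 0.0731) and Rpl10a from 0.40 to 0.23 (adjusted p = 0.237). The libraries of both groups overlapped at Pdx1 (−0.17, adjusted p = 0.142) and at no other gene named in this comparison.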

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

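Of the tests in this part, those of the mapping batch and of copies for the ribosomal protein genes, and that of larger IP fold changes for the cell cycle genes, were chosen only after the results were seen. The mapping batch itself was also defined after the data were seen.

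By the test of the difference itself, the effect of the Pdx1 siRNA differed between IP and total RNA at 29 genes. Among them the log2 difference, IP minus total, was 1.15 at Scand1, 1.11 at H2aj, 1.11 at Srebf1, 1.09 at Prr7, 1.03 at Cnbd2 and 1.00 at Il4i1b. It was −1.17 at Blm, −0.85 at Bub1, −0.84 at Smarcal1, −0.75 at Mki67, −0.71 at Melk and −0.57 at E2f8. Nkx2-2 differed by 0.58, Jund by 0.86, Junb by 0.74 and Uqcrq by 0.72. Among gene lists the median difference was 0.16 for the ATF4 and integrated stress response, 0.15 for apoptosis and p53, 0.26 for immediate early genes, −0.49 for the cell cycle, −0.29 for cytosolic ribosomal proteins, 0.17 for oxidative phosphorylation and 0.38 for small nucleolar RNA host genes. With an estimated correlation camera called 0 of these lists. The ribosomal protein median turned to 0.15 with the mapping batch as a term.

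Other splits of the libraries within each fraction were drawn, 100 of the 200 possible, and 5 of them, the real split included, gave at least 29 genes, while 95 gave 0. The highest other split gave 8618 genes. The 4 other splits, with 2625 to 8618 genes, set most NT libraries of a fraction together with most Pdx1 siRNA libraries of the other. They point to a structure of the samples, since the siRNA effects of both fractions then add up in the interaction. The count of splits therefore does not exclude chance, nor does it speak for it.

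Of 78 cytosolic ribosomal protein genes, 15 were called lower by 2-fold or more in IP RNA after Pdx1 siRNA, while their median in total RNA was 0.11. Loss of ribosomal protein mRNAs from the IP fraction cannot be told apart: the 25 members without a near-identical copy had a median of 0.27 with the mapping batch as a term, but that term leaves NT IP replicate 3 as the only NT IP library compared, and these members lay 0.50 lower in it than in replicates 1 and 2. A difference in read mapping between the sets of libraries is a candidate explanation: 216 genes with copies outside the ribosomal proteins, uncalled in total RNA, part the IP libraries into the same sets. With a batch term set from them 0 of the 15 stayed lower by 2-fold or more (median −2.72 before, 0.09 after). However, all 15 were already lower by more than 2-fold in NT IP replicate 3 than in replicates 1 and 2, and only replicate 3 is then compared. The result largely restates those low counts and cannot tell read mapping from another cause of them. Whether shared reads decide which members are affected cannot be told apart, since 10 of 53 members with a copy (18.9%) and 5 of 25 without (20%) were among the 15, but 1 of the 9 with under 10% matched elsewhere (11.1%). Over all genes, ribosomal protein genes included, the share called lower by 2-fold or more in IP RNA rose with the part matched elsewhere. It was 4.4% with under 10% matched, 9.2% with 10% to under 50% and 19.1% with 50% or more. In total RNA these shares were 3.6%, 4.5% and 5%. The labels do not say how these libraries were processed, so what differs in NT IP replicate 3 and the Pdx1 siRNA IP libraries stays open.

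Cell cycle genes fell further in IP than in total RNA, with a median difference of −0.49. The mapping batch cannot be told apart with certainty: the median was −0.46 with the batch as a term (31 of 33 members below 0) and NT IP replicate 3 lay −0.06 from replicates 1 and 2, but replicate 3 is then the only NT IP library compared. Transcript length and GC content are argued against by a median of −0.48 after their trend over all genes was taken off (32 of 33 below 0). Larger fold changes in the IP libraries cannot be told apart from an effect on these genes: 707 other genes that changed 2-fold or more in both fractions gave a slope of 1.10, which leaves a median of −0.34, but the 362 that fell gave 1.17, which leaves −0.22 (31 of 33 below 0, bootstrap interval −0.30 to −0.18), short of the limit of −0.25. With an estimated correlation between genes the list's adjusted p was 0.091, so the members cannot be counted as independent evidence.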

How the results depend on the processing

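Alternatives added after the data were seen are the mapping batch as a term, the IP libraries of a single mapping batch, genes with copies left out and the lowest transcript per gene. Over the 27 settings, 2996 of 3144 values of named genes under alternatives chosen beforehand kept their direction and their side of the threshold, 108 lost the call, 40 gained it and 0 reversed. Under added alternatives 675 of 724 kept both, 39 lost the call, 5 gained it and 5 reversed. Of the set tests of called lists, 472 of 508 under planned and 112 of 115 under added alternatives kept both. The expression filter against none could change nothing, since it removes 0 genes, and a filter on CPM removed 223.

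Counts of changed genes stayed within 1.5 times in total RNA and between IP and total RNA under every setting run, and in IP RNA except within a single mapping batch (4900 against 7542), where fewer libraries enter. The interaction count of 29 moved to 52 with upper-quartile factors, 327 with DESeq2, 54 without Ins1 and Ins2, 97 without genes that have copies, and 5 both with the mapping batch as a term and within a single mapping batch. Leaving out a library gave 4 to 571 interaction genes. The cause was not tested. The correlation of both siRNA effects across genes, 0.821, was 0.913 with the mapping batch as a term and 0.913 within a single mapping batch, and 0.787 to 0.840 with a library left out.

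With an estimated correlation, camera called 3 lists in total RNA, 3 in IP RNA, and 0 each in the interaction and in IP against total RNA under NT and Pdx1 siRNA, against 7, 7, 7, 5 and 6 with the preset correlation. The estimate allows for members that vary together. The fry test, which does not compare a list with other genes, called 16, 17, 4, 13 and 16. Reversed with the mapping batch as a term were the ribosomal protein list of the interaction (0.15, and 0.14 within a single mapping batch), Rpl37 in IP RNA (0.02 in both), and, for IP against total RNA after Pdx1 siRNA, Lars2 (0.27), Rpl32l (1.30) and Rpl35 (0.81). The size of the Lars2 fold in IP RNA rests on NT IP replicate 2 (−2.51 without it, still past the test). The batch term at Lars2 is set by the NT IP libraries, where replicate 2 held 354753 counts and replicates 1 and 3 held 13833 and 5545. The Lars2 reversal may therefore rest on replicate 2 and not on read mapping. A fit with the term and without that library was not run.

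Replicate numbers are shared by the groups, but the labels do not say that they pair cultures. Of 18 same-numbered pairs of libraries 9 had deviations from the group mean that correlated above 0.1 (−0.105 to 0.514), and 10 of 12 libraries correlated best with their own number, a hint from the data that the design does not state. With the replicate number as a block the interaction count was 373, and 367 with a block within each siRNA; in total RNA the block gave 7231 genes and in IP RNA 7926.

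On simulated data with these depths, changes of 1.5-fold were found in 82% of cases in total RNA, 90% in IP RNA and 34% in the interaction. Few genes were changed in the simulation, with 155 calls in total RNA against 6696 in the data, and it held no mapping batch. These rates therefore need not hold for the real comparisons. Genes that passed no test can hold changes of this size.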

Other observations

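The mapping batch used in this part was defined only after the data were seen; the tests of length and GC content and of other splits were set beforehand. Several further gene groups changed in part after Pdx1 depletion without a call by camera for the list as a whole. By fry, which does not compare with other genes, 9 lists passed in total RNA that camera did not call. Those were the lists of exocrine markers (adjusted p = 2.8e-06), interferon response (8.5e-06), aminoacyl-tRNA synthetases (0.001), nuclear-retained RNAs (0.002), glucose sensing (0.00661), genes that beta cells normally keep off (0.0193), beta-cell transcription factors (0.0228), PDX1 targets (0.035) and cholesterol synthesis (0.0353). In total RNA 8 of 19 interferon response genes rose and 3 fell (8 and 3 adjusted over the list alone; median 0.28, camera adjusted p = 0.171), and Ifit2 was among those that fell (−1.11). Of 17 immediate early genes 5 rose and 8 fell (6 and 8 adjusted over the list alone; median −0.24, camera adjusted p = 0.927), with Egr1 at −1.32 and the nuclear receptor gene Nr4a2 at 1.09. Of 14 genes that beta cells normally keep off, 3 rose and 7 fell (3 and 7 adjusted over the list alone; median −0.24, camera adjusted p = 0.802). Ldha (−2.15) and Igfbp4 (2.39) lay at opposite ends of this list. Exocrine pancreas markers gave 5 of 7 higher and 1 lower (5 and 1 adjusted over the list alone; median 0.56, camera adjusted p = 0.0742), with the osteopontin gene Spp1 at 1.42. Progenitor markers gave 3 of 5 higher and 1 lower (3 and 1 adjusted over the list alone; median 0.30, camera adjusted p = 0.704), with Myc lower (−0.69).

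In total RNA 3 of 78 ribosomal protein genes rose and 0 fell (0 and 0 adjusted over the list alone; median 0.12, camera adjusted p = 0.397), and Rpl10a was at −0.07 (adjusted p = 0.499). In IP RNA 14 ribosomal protein genes rose, Rpl3 (0.60) among them, and 27 fell (14 and 26 adjusted over the list alone; median −0.15, camera adjusted p = 0.629). With the mapping batch as a term that median was 0.23. Translation factors gave 8 of 43 higher and 12 lower in total RNA (8 and 11 adjusted over the list alone; median −0.08, camera adjusted p = 0.911). Oxidative phosphorylation genes gave 2 of 46 higher and 11 lower (2 and 10 adjusted over the list alone; median −0.09, camera adjusted p = 0.522). Cholesterol synthesis genes gave 3 of 22 higher and 6 lower (3 and 6 adjusted over the list alone; median −0.03, camera adjusted p = 0.521), with the sterol carrier gene Stard4 at −1.08. Small nucleolar RNA host genes gave 2 of 11 higher and 3 lower (2 and 3 adjusted over the list alone; median 0.13, mean −0.01, camera adjusted p = 0.927). Nuclear-retained long non-coding RNAs gave 4 of 9 higher and 1 lower (5 and 1 adjusted over the list alone; median 0.30, camera adjusted p = 0.215). In IP RNA Neat1 (1.09) and Meg3 (0.93) rose.

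Medians and camera pointed in opposite directions for a few lists that camera did not call between IP and total RNA. The genes that beta cells keep off had a median of −0.20 with NT and −0.31 with Pdx1 siRNA while camera pointed up (adjusted p = 0.775 and 0.785). Exocrine markers had a median of 0.11 and a mean of −0.19 with NT siRNA, and 0.23 and −0.21 with Pdx1 siRNA, with camera pointing down (adjusted p = 0.775 and 0.785), though fry called them (adjusted p = 0.00411 and 0.0112). Immediate early genes with Pdx1 siRNA had a median of −0.09 while camera pointed up (adjusted p = 0.785). In the interaction such differences in sign had medians of −0.05 to 0.01, as for other islet endocrine markers (median −0.05, mean 0.02).

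The composition of IP against total RNA in NT cells, with oxidative phosphorylation mRNAs at a median of 0.92 and nuclear-retained long non-coding RNAs at −0.99, was set against technical trends. The mapping batch is argued against as the whole cause, with medians of 0.91 and −0.92 when it is a term. A trend on transcript length and GC content explained 37.4% of the variance of the IP to total ratio over all genes. After it was taken off the oxidative phosphorylation median was 0.42 (45.9% of its value, bootstrap interval 38.7% to 53.4%), with 4 of 46 members below 0. The trend did not take off the whole difference, but the parts of length and ribosome loading cannot be told apart for these genes, whose median length is 903 bases against 2966 for all. The long non-coding median was −0.94 after that step, with a bootstrap interval from −1.74 to 0.26 over 9 members that leaves it open. Even so, Malat1 (−2.27 before, −1.60 after), Neat1 (−1.996 and −1.92) and Meg3 (−2.76 and −1.74) stayed low. Rian went from −0.99 to −0.16, Tug1 from −0.07 to 0.40 and Peg13 from −0.07 to 0.26. Kcnq1ot1 (−1.05 and −1.11), Mirg (−0.43 and −0.94) and Airn (−0.42 and −0.79) moved lower. Short mRNAs may be recovered more readily, or be more often on ribosomes, and retention in the nucleus, a known property of these RNAs, was not measured here.

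Splits of the 6 libraries of each comparison of groups are too few for a share under 0.1, since 3 against 3 libraries allow 10 splits. In total RNA 1 of 10 splits, the real one with 6696 genes, reached its count and the highest other gave 0. The same held in IP RNA (7542 against 0), in IP against total RNA with NT siRNA (8810 against 0) and with Pdx1 siRNA (9490 against 0). The other splits mix libraries of both groups, so the difference between the groups enters their spread. Counts of 0 there follow from this and are no evidence against chance.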
